A study of Mus musculus with 16 samples.

How the data were processed

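RNA was measured in the aorta of ApoE-/- mice, which lack apolipoprotein E and are widely used as a model of atherosclerosis. Per the labels, the mice were 8 weeks old when they were put on a Western diet or a normal purified diet, and the aorta was taken after 6 or 22 weeks, at an age of 14 or 30 weeks. There were 4 groups of 4 libraries, 16 in all. The genotype field of the labels reads "APOE knockdown", while the design text names ApoE-/- mice, and no wild-type group was included. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with an Illumina RNA-seq preparation kit. Neither strand nor the removal of ribosomal RNA is given in the sources used here. One sample label points to the value column of another replicate of its group, so columns were matched by sample title.

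A single table was deposited for the whole series. It held 70603 loci, with a value in FPKM (fragments scaled by transcript length and sequencing depth) and an estimated count for each library, per the file headers. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9, checked with FastQC and placed on the mouse genome build GRCm38. The aligner, the counter and the annotation release are not given in the sources used here. The identifiers of 45150 loci have the form that StringTie gives to merged transcript models, so 1 gene can have several loci, and overlapping genes can share 1 locus, such as Apoe with Tomm40. The deposited estimated counts were whole numbers, but their low values piled up in steps of about 4. The value 4 occurred 35277 times, against 14716 times for 3 and 9394 times for 5. A sequenced fragment may thus have counted as about 4 units, in which case a deposited count is not a number of fragments. The counter is not given, so this was not tested. The deposited FPKM values were set to 1e-04 wherever the count was 0.

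Of all loci, 66889 named a gene. The other 3714 held 0.606% of the counts and were left out of library sizes and tests. Loci with a deposited FPKM of 1 or more in at least 4 libraries were kept, which left 24091 loci and 98% of the counts. Of these, 22653 named 1 gene and 1438 named 2 or more. Locus coordinates were compared with a GENCODE annotation of GRCm38, in which 97.25% of 63068 loci naming 1 gene overlapped that gene. The counts of loci on a chromosome labelled MT summed to 0 in every library. Whether any locus carries that label, or mitochondrial loci carry another, was not checked.

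The plan written before the data were examined assumed that FPKM values alone would be present and named limma on log2(FPKM + 0.5). Because estimated counts were deposited, the main test was edgeR's quasi-likelihood test on those counts, which were already whole numbers, with the planned filter and the planned model of 4 group means over all 16 libraries. Library sizes were scaled by the trimmed mean of M-values (TMM). The limma test was kept as an alternative. Tests were two-sided, with Benjamini-Hochberg adjustment over the 24091 loci, and a locus passed at an adjusted p under 0.05. The comparisons were Western against normal diet at 6 weeks and at 22 weeks, the difference of these diet effects, and 22 against 6 weeks on each diet. A log2 fold change is given with its standard error (SE), taken from the fold change and the F statistic. Values per group are TMM-scaled counts per 1e6 counts (CPM), as mean ± SD. Beside the counts of passing loci stands the share of loci for which the 4 libraries of one group all lay above the 4 of the other, which chance alone gives for 2.86% of loci.

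The same plan fixed 30 gene lists for cell types of the aorta and its surroundings and for pathways of lipid handling, lysosomes, autophagy and stress, of which 28 kept at least 5 measured members. Where a gene had several loci, the locus with the highest mean FPKM stood for it. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 28 lists within each comparison. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. List members were also adjusted over the list alone. A score of a list is the mean log2 CPM of its members after centring each member over the 16 libraries. Scores were compared between groups by exact permutation of the 8 libraries of a comparison, for which the smallest p is 0.0286. For lists that passed, each library whose omission moved the score difference by over 1.5 times is named, a check added after the values were seen.

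Genes named by fold were the 10 with the largest change in each direction for each diet comparison, and 5 for the other comparisons. Only passing loci with a mean FPKM of 1 or more and an official symbol entered. In the diet and time comparisons they also had to show no overlap between the groups, which was not asked for the difference of the diet effects. Where fewer than 5 qualified in a direction, loci with the lowest p filled the list to 5. For each list that passed, and for 6 macrophage, lysosome, autophagy and smooth muscle lists in every diet comparison, the 4 members with the lowest p were named. The text gives a part of them, and further genes are marked as chosen after their values were seen. Some genes that met the rule are not reported here.

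The test was tried on simulated counts for the 24091 loci, with 50 loci changed at each of 4 folds. The changed loci were drawn from those with a mean count of 100 or more. In the simulation of the 6-week diet comparison, 12% of the loci changed by a fold of 1.5 were recovered, 56% of those changed by a fold of 2, 96% at a fold of 4 and 100% at a fold of 8, with 3 false calls. In that of the 22-week comparison the shares were 16%, 60%, 98% and 100%, with 7 false calls. Most changes under a fold of 2 were therefore below what 4 libraries per group could resolve at such loci. Recovery at loci of lower counts was not measured.

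Total estimated counts ranged from 45.25 to 81.4 per library, in units of 1e6. If a fragment counted as about 4 units, these totals stand for fewer fragments than counts. Time could not be separated from library preparation: the library codes in the labels fell into 1 series for 6 weeks and another for 22 weeks. It could not be separated from age either. Alternatives covered pseudocounts, filters, scalings, the samples entering the fit, a block on the replicate number, each library left out in turn, DESeq2 1.42.0, correction for GC content and for length, and division of the counts by 4. Those chosen after seeing the data are named where they are reported. Analyses used R 4.3.3, edgeR 4.0.16 and the data.table package, version 1.17.8.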

Results

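Transcript levels were measured by RNA sequencing in the aorta of ApoE-/- mice, which lack apolipoprotein E, after 6 or 22 weeks on a Western diet or on a normal purified diet, with 4 libraries in each of 4 groups. The series addresses genes linked to macrophage autophagy in atherosclerosis, the build-up of lipid-filled plaque in the artery wall. Total estimated counts, in units of 1e6, averaged 73.22 ± 9 in the normal-diet and 69.44 ± 3.25 in the Western-diet libraries at 6 weeks, and 57.98 ± 8.89 and 63.29 ± 6.69 at 22 weeks (mean ± SD, n = 4 each), with a range of 45.25 to 81.4 over all libraries. Of 70603 deposited loci, 24091 passed the expression filter. The first principal component of the 2000 most variable loci held 38.7% of their variance and separated the 8 libraries of 6 weeks from the 8 of 22 weeks. Coordinates are of the mouse genome build GRCm38. Adjusted p values of loci are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists are from camera.

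The targeted gene, Apoe, could not be read on its own, because the deposited locus on chromosome 7 (19696109 to 19715438) joins it with its neighbour Tomm40, a pore protein of the mitochondrial outer membrane. This locus stood at 36.1 ± 1.47 CPM on normal and 38.3 ± 2.98 CPM on Western diet at 6 weeks, and at 78.7 ± 9.67 and 88.2 ± 10.2 CPM at 22 weeks (mean ± SD, n = 4 each). The series holds no wild-type aorta, so these values check neither the knockout nor the labels.

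After 6 weeks, genes of fatty acid synthesis were lower in the aorta of Western-fed mice. Acly, which makes the cytosolic acetyl-CoA used for lipid synthesis, fell by 2.04 ± 0.32 on the log2 scale (SE), from 3080 ± 429 to 749 ± 214 CPM (SD, n = 4 each; adjusted p = 0.0119). Thrsp, a regulator of lipogenesis, fell from 1120 ± 163 to 396 ± 87.6 CPM (log2 fold change -1.50 ± 0.25, adjusted p = 0.0178), and Me1, a malic enzyme that supplies NADPH, from 1070 ± 234 to 305 ± 93.3 CPM (-1.80 ± 0.33, adjusted p = 0.0307). Fasn, the fatty acid synthase, stood at 14700 ± 1750 CPM on normal and 5780 ± 1100 CPM on Western diet and did not pass over all loci (adjusted p = 0.0703). The 11 measured genes of the list had a median log2 fold change of -1.02. Of these, 3 fell over all loci tested and 7 fell when adjusted over the list alone, while 10 of 11 had a negative fold change. The list passed (camera adjusted p = 1.5e-19), but not with an estimated correlation, where the adjusted p was 0.07. The adipocyte marker list had a median of -0.31 (camera adjusted p = 0.0075, and adjusted p = 0.8 with an estimated correlation), and 0 of its 16 members passed over all loci in this edgeR test.

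**Figure D1:**
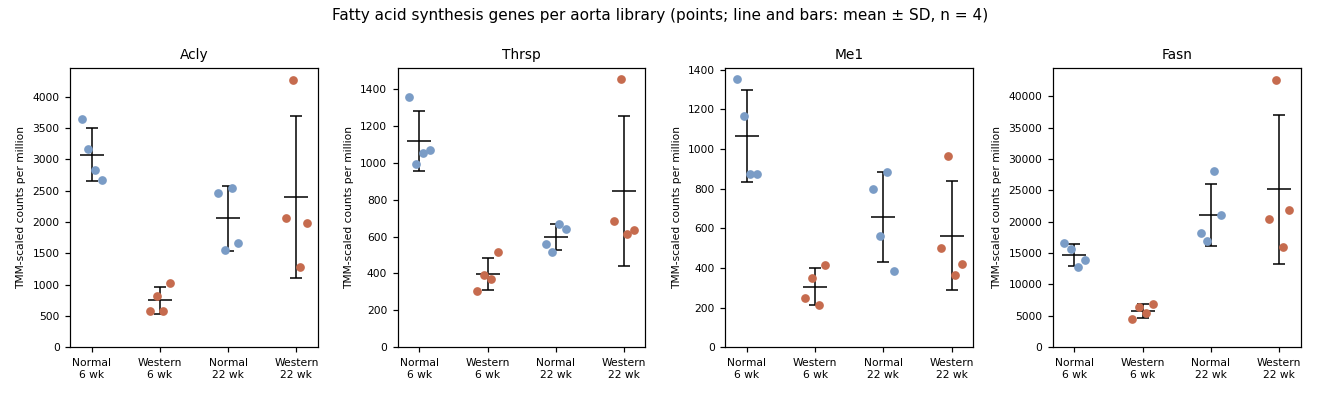
CPM of Acly, Thrsp, Me1 and Fasn in each library, by diet and time, on linear axes that start at 0. Points are libraries, and lines with bars are the mean ± SD of 4 libraries. At 6 weeks all Western-diet libraries lay below all normal-diet libraries for these 4 genes, while at 22 weeks the diets overlapped.

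Other genes of carbohydrate and lipid handling fell at 6 weeks too. Slc2a5, the fructose transporter GLUT5 (chromosome 4, 150119283 to 150144169), fell from 24.2 ± 7.24 to 2.1 ± 0.609 CPM (log2 fold change -3.52 ± 0.46, adjusted p = 0.00318). Slc25a10, the mitochondrial dicarboxylate carrier, fell from 39.7 ± 5.7 to 9.96 ± 2.06 CPM (-1.99 ± 0.19, adjusted p = 0.000235). Mogat2, which acylates monoacylglycerol (-2.57 ± 0.31, adjusted p = 0.00238), the fatty acid binding protein Fabp5 (-1.82 ± 0.30, adjusted p = 0.015) and a locus of the transketolase gene Tkt without an annotated transcript (-1.89 ± 0.33, adjusted p = 0.0192) fell as well. A short locus named Nfrkb, also without an annotated transcript (chromosome 9, 31422637 to 31425320) fell by 2.22 ± 0.22 on the log2 scale (adjusted p = 0.000277). It lies next to that of Tmem45b (31426196 to 31464462), which fell by 1.92 ± 0.25 (adjusted p = 0.00329), so reads of Tmem45b in the locus named Nfrkb are not excluded. Genes that rose included Cntfr, a receptor subunit for ciliary neurotrophic factor, from 3.04 ± 0.51 to 11.7 ± 4.7 CPM (1.95 ± 0.29, adjusted p = 0.00869). Dio2, which activates thyroid hormone and is a brown fat gene, rose from 88.8 ± 19.5 to 246 ± 65.1 CPM (1.47 ± 0.25, adjusted p = 0.0192), and the protease gene Adam12 rose by 1.63 ± 0.32 (adjusted p = 0.0483).

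Genes of the circadian clock differed between the diets at 6 weeks. Hlf, a transcription factor driven by the clock, fell from 31.8 ± 2.93 to 13.1 ± 1.16 CPM (-1.28 ± 0.16, adjusted p = 0.00318), and Per3, a period gene, from 99.6 ± 28.1 to 30 ± 7.3 CPM (-1.73 ± 0.33, adjusted p = 0.0396). Of 12 measured clock genes, 2 fell over all loci, and 6 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.00081, and adjusted p = 0.07 with an estimated correlation). Neither the labels nor the design text gives the time of day at which tissue was taken.

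The autophagy and lysosome lists did not pass at 6 weeks. The 31 genes of the autophagy core machinery had a median log2 fold change of 0.03 (camera adjusted p = 0.26), the 27 autophagy receptors and regulators one of 0.00 (adjusted p = 0.63) and the 35 lysosome genes one of 0.04 (adjusted p = 0.63). In edgeR, 0 genes of these 3 lists passed over all loci, and 1 autophagy core gene passed when adjusted over the list alone. Wipi2, which binds membrane lipids at the forming autophagosome, had the lowest p among them, with a log2 fold change of 0.73 ± 0.17 (adjusted p = 0.0964). For the 18 lipid-laden macrophage genes the test pointed down (adjusted p = 0.57) although the median was 0.20, and Fabp5 was the member that fell.

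Other lists that passed at 6 weeks are given beside markers of other tissues, which varied between single libraries. Rag1, Acta1, Ucp1 and Alb were chosen as such markers after their values were seen. T and NK cell markers had a median of 1.98 (camera adjusted p = 0.0011, and adjusted p = 0.79 with an estimated correlation), and their score difference of 1.63 was 0.92 without Western-diet replicate 1. The locus of Rag1, an enzyme of developing lymphocytes, is shared with B230118H07Rik. It stood at 317, 68.3, 24 and 22.7 CPM in Western-diet replicates 1 to 4 of that time, against 12.4 to 17.3 CPM on normal diet. All Western-diet libraries thus lay above all normal-diet libraries. The 9 cell division genes, which had a median of 1.76 (camera adjusted p = 4.7e-05, and adjusted p = 0.62 with an estimated correlation), passed in 7 cases adjusted over the list alone. Their score was 2.11 in Western-diet replicate 1, the library highest in Rag1, against -0.07, -0.34 and -0.66 in the other Western-diet and -0.94 to -0.46 in the normal-diet libraries, and the score difference of 1.04 was 0.42 without that library. Skeletal muscle markers had a median of -1.54 (camera adjusted p = 1.5e-07, and adjusted p = 0.37 with an estimated correlation), and the muscle actin Acta1 stood at 35.2 ± 18.4 CPM on normal and 7.37 ± 4.63 CPM on Western diet. The muscle score difference of -1.86 was -1.02 without Western-diet replicate 4. B and plasma cell markers had a median of -1.92 (camera adjusted p = 0.01, and adjusted p = 0.8 with an estimated correlation), but their score difference of -1.21 was -0.24 without normal-diet replicate 2. The remaining lists that passed were interferon-stimulated genes (median -0.42), contractile smooth muscle genes (-0.27), immediate early genes (0.28), heat shock and unfolded protein genes (0.44) and macrophage markers (0.33). With an estimated correlation their adjusted p values were 0.79, 0.79, 0.62, 0.29 and 0.8. The interferon score difference of -0.36 was -0.09 without normal-diet replicate 2 and -0.61 without replicate 3 of that diet. The macrophage score difference of 0.29 was 0 without Western-diet replicate 3 and 0.43 without normal-diet replicate 2, and that of immediate early genes, 0.34, was 0.20 without Western-diet replicate 3.

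In all, 68 of 24091 loci passed at 6 weeks, 15 higher and 53 lower on Western diet (237 higher and 221 lower of 458 with DESeq2), and the diets did not overlap in 7.39% of loci against 2.86% by chance. Of the 28 lists 12 passed with the preset correlation and 0 with an estimated correlation in camera, with 2 in fry. The number of passing loci was 24 without the 4 libraries highest in thymocyte or B cell genes, an alternative chosen after seeing the data. It was 30 without Western-diet replicate 2 or normal-diet replicate 1, and 44, 43 and 41 without normal-diet replicates 2, 3 and 4.

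After 22 weeks, lysosome genes and genes of lipid-laden macrophages were higher in the aorta of Western-fed mice. Lipa, the lysosomal acid lipase that hydrolyses cholesteryl esters (chromosome 19, 34492318 to 34527474), rose from 64.7 ± 8.78 to 118 ± 13.2 CPM (log2 fold change 0.87 ± 0.11 SE, adjusted p = 0.0179; SD and n = 4 for the levels). The locus of the lysosomal protease Ctsd, shared with Ifitm10, rose from 1010 ± 147 to 1730 ± 65.4 CPM (0.78 ± 0.12, adjusted p = 0.0207). Psap, the precursor of the saposins, rose from 1520 ± 232 to 2410 ± 144 CPM (0.66 ± 0.11, adjusted p = 0.0317). At 6 weeks Lipa had stood at 104 ± 7.95 CPM on normal and 88.6 ± 5.4 CPM on Western diet. Its level on normal diet was thus lower at 22 than at 6 weeks, while that on Western diet was higher. Of 35 lysosome genes 5 rose over all loci and 18 rose when adjusted over the list alone, with 32 of 35 positive and a median of 0.33 (camera adjusted p = 2.5e-22). The list passed with an estimated correlation as well (adjusted p = 0.013).

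The 18 lipid-laden macrophage genes all had a positive fold change, with a median of 0.82. Lipa and the Ctsd locus, which are on both lists, rose over all loci, and 12 rose when adjusted over the list alone (camera adjusted p = 5.7e-18, and adjusted p = 0.013 with an estimated correlation). Trem2, a lipid receptor of macrophages, stood at 19.3 ± 8.64 CPM on normal and 47.3 ± 6.52 CPM on Western diet, and the Gpnmb locus, shared with Malsu1, at 306 ± 139 and 736 ± 93.8 CPM. Trem2 and Gpnmb were chosen after their values were seen, and neither passed over all loci. The lysosome and lipid-laden macrophage lists also share Cd63 and Atp6v0d2, so their results are not independent. The 20 general macrophage markers had a smaller median of 0.40, and in edgeR 0 of them passed, either over all loci or over the list alone (camera adjusted p = 0.00079, and adjusted p = 0.45 with an estimated correlation). The macrophage score difference of 0.43 was 0.25 without normal-diet replicate 2. C1qc, a complement component made by macrophages, had the lowest p of them, with a log2 fold change of 1.33 ± 0.45 (adjusted p = 0.184).

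**Figure D2:**
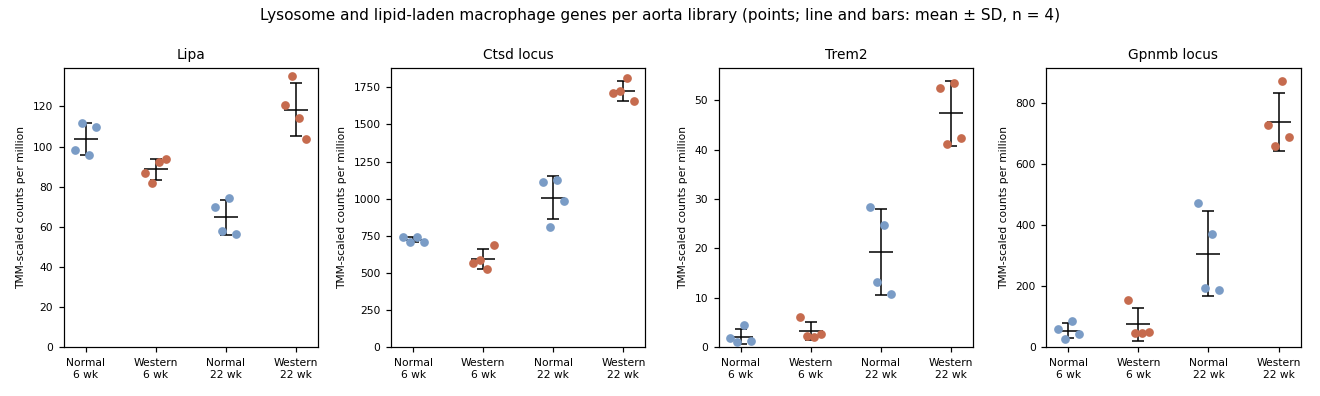
CPM of Lipa, the Ctsd locus, Trem2 and the Gpnmb locus in each library, by diet and time, on linear axes that start at 0. Points are libraries, and lines with bars are the mean ± SD of 4 libraries. At 22 weeks all Western-diet libraries lay above all normal-diet libraries for these 4 loci.

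The 31 genes of the autophagy core had a median of 0.10 with 24 of 31 positive (camera adjusted p = 0.024, and adjusted p = 0.45 with an estimated correlation), and in edgeR 0 passed over all loci or over the list alone. Map1lc3b, an LC3 protein of the autophagosome membrane, had a log2 fold change of 0.96 ± 0.34 (adjusted p = 0.205). The 27 receptors and regulators had a median of 0.16 (camera adjusted p = 0.00032, and adjusted p = 0.25 with an estimated correlation), and 3 rose when adjusted over the list alone. Tex264, a receptor for autophagy of the endoplasmic reticulum, had the lowest p of them (0.50 ± 0.15, adjusted p = 0.137).

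Cholesterol genes were also higher at 22 weeks. Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, rose from 93.2 ± 21.6 to 305 ± 136 CPM (1.71 ± 0.27, adjusted p = 0.0207). It was the member of the cholesterol synthesis and uptake list that rose over all loci, and 4 of 20 rose when adjusted over the list alone (median 0.45, camera adjusted p = 1.3e-06, and adjusted p = 0.37 with an estimated correlation). Of 12 genes of cholesterol efflux and LXR targets, 7 rose when adjusted over the list alone (median 0.37, camera adjusted p = 1.4e-05, and adjusted p = 0.081 with an estimated correlation). The exporter gene Abcg1 was at 115 ± 23.7 CPM on normal and 195 ± 24 CPM on Western diet (0.76 ± 0.17, adjusted p = 0.0704). The fatty acid synthesis list had a median of 0.26 (camera adjusted p = 0.013, and adjusted p = 0.52 with an estimated correlation), but its score did not separate the diets (exact permutation p = 0.486). The score was 1.10 in Western-diet replicate 2 and between -0.14 and 0.13 in the other Western-diet libraries, against -0.24 to 0.24 on normal diet, and the score difference of 0.30 was 0.04 without that replicate.

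Genes of brown fat and mitochondria were higher on Western diet at 22 weeks, together with markers of muscle. Fabp3, a fatty acid binding protein of heart, muscle and brown fat, rose from 7.7 ± 4.4 to 46.2 ± 15.6 CPM (2.58 ± 0.36, adjusted p = 0.0201), and the cytochrome oxidase subunit Cox8b from 47.5 ± 20.7 to 149 ± 57 CPM (1.65 ± 0.29, adjusted p = 0.0367). These were the 2 of 13 brown adipocyte genes that rose over all loci, and 10 rose when adjusted over the list alone (median 1.08, camera adjusted p = 3e-17, and adjusted p = 0.067 with an estimated correlation). All 27 oxidative phosphorylation subunits were positive (median 0.93) and rose when adjusted over the list alone, although 0 passed in edgeR over all loci (camera adjusted p = 2.8e-36, and adjusted p = 0.079 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, lay between 219 and 828 CPM on normal and between 823 and 2090 CPM on Western diet. Skeletal muscle markers had a median of 2.71 (camera adjusted p = 1.6e-11, and adjusted p = 0.11 with an estimated correlation). Acta1 reached 112, 88.3 and 68.5 CPM in Western-diet replicates 1 to 3 and 11.9 CPM in replicate 4, against at most 16.8 CPM on normal diet. Adipocyte markers had a median of 0.44 (camera adjusted p = 0.00017, and adjusted p = 0.45 with an estimated correlation), and their score difference of 0.46 was 0.29 without Western-diet replicate 2.

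The smooth muscle lists had medians of opposite sign at 22 weeks. Contractile smooth muscle genes had a median of -0.36 with 18 of 20 negative (camera adjusted p = 1.8e-05, and adjusted p = 0.45 with an estimated correlation), and in edgeR 0 passed over all loci or over the list alone. The score difference of -0.33 was -0.16 without Western-diet replicate 2 and -0.18 without normal-diet replicate 2. The smooth muscle myosin Myh11 had a log2 fold change of -0.51 ± 0.21 (adjusted p = 0.276). Modulated smooth muscle and osteochondrogenic genes had a median of 0.39, and 7 of 15 rose when adjusted over the list alone (camera adjusted p = 6.3e-05, and adjusted p = 0.11 with an estimated correlation). Among them Col2a1, a collagen of cartilage, lay between 94.2 and 393 CPM on Western diet and between 2.21 and 85.3 CPM on normal diet (3.13 ± 0.94, adjusted p = 0.14).

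The other lists that passed at 22 weeks were heat shock and unfolded protein genes (median 0.49), cytokines, chemokines and inflammasome genes (0.49), antigen presentation genes (0.48) and T and NK cell markers (0.49). With an estimated correlation their adjusted p values were 0.11, 0.33, 0.52 and 0.58. The antigen presentation score difference of 0.51 was 0.30, 0.26 and 0.91 without normal-diet replicates 1, 2 and 4, and that of T and NK cell markers, 1.23, was 0.81, 0.75 and 2.07 without the same libraries. The Rag1 locus stood at 109, 13.9, 14.6 and 53.3 CPM in Western-diet replicates 1 to 4 of this time, against 3.52 to 6.4 CPM on normal diet. All Western-diet libraries thus lay above all normal-diet libraries here too.

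Genes that fell at 22 weeks included Selenow, a selenoprotein, from 117 ± 8.43 to 67.4 ± 3.91 CPM (-0.80 ± 0.11, adjusted p = 0.0195). Hsd11b1, which regenerates active glucocorticoid, fell from 105 ± 16.5 to 60.9 ± 6.63 CPM (-0.78 ± 0.13, adjusted p = 0.0317). A locus of Bcl2 without an annotated transcript fell by 0.66 ± 0.12 (adjusted p = 0.0397).

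In all, 55 loci passed at 22 weeks, 42 higher and 13 lower on Western diet. Loci with an annotated transcript gave 42 higher and 5 lower, and those without one 0 higher and 8 lower, with a median log2 fold change of -0.15 over all of the latter. Loci without an annotated transcript held 6.72% of counts on Western and 7.89% on normal diet. The diets did not overlap in 7.51% of loci against 2.86% by chance. Of the 28 lists 18 passed with the preset correlation, 2 with an estimated correlation and 9 in fry. The number of passing loci depended on single libraries: it was 0 without normal-diet replicate 2, 26 without replicate 1 and 429 without replicate 4 of that diet, 20, 16, 35 and 36 without Western-diet replicates 1 to 4, and 318 without the 4 libraries highest in thymocyte or B cell genes. It was also 0 when the fit held the 8 libraries of this time alone in edgeR, against 829 with DESeq2 on all libraries and 3437 loci at an unadjusted p under 0.05 in the main test.

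**Figure D3:**
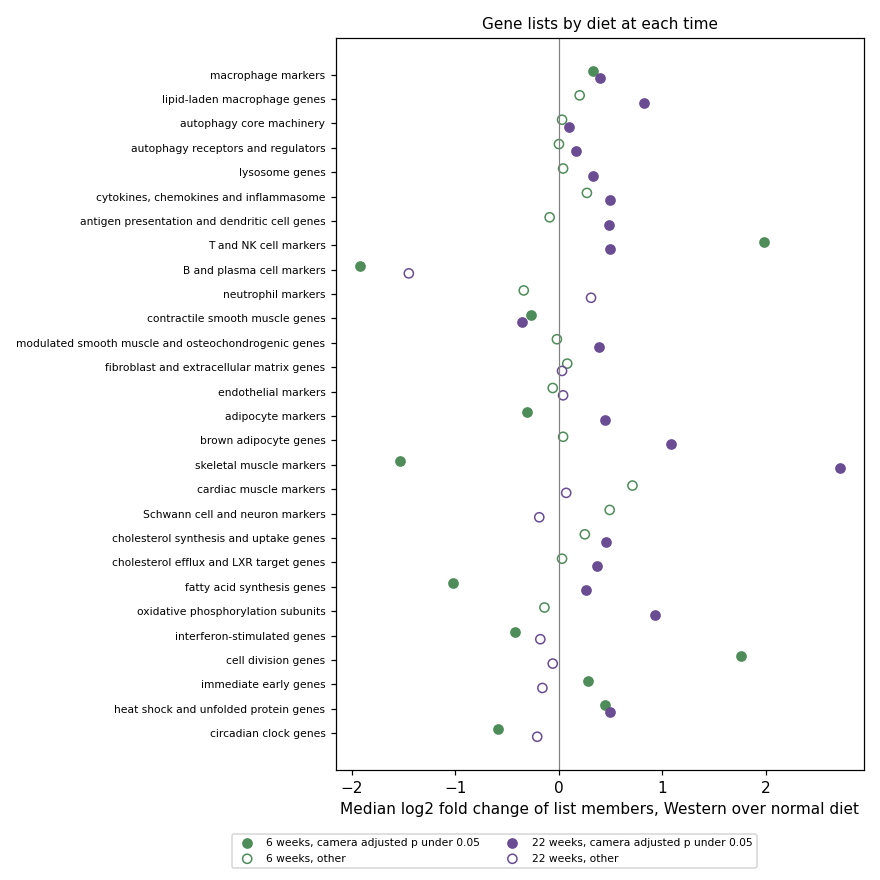
Median log2 fold change, Western over normal diet, of the measured members of each of 28 gene lists at 6 weeks and at 22 weeks. Filled points passed camera with a preset correlation (12 lists at 6 weeks, 18 at 22 weeks) and open points did not; with an estimated correlation 0 passed at 6 weeks and 2, lysosome and lipid-laden macrophage genes, at 22 weeks.

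The effects of diet at both times were compared directly. Hsd11b1 fell at both, from 109 ± 5.11 to 40.4 ± 7.28 CPM at 6 weeks, and was the single locus that passed at both times in the same direction, against 0.0286 expected by chance (one-sided Fisher's exact test, p = 0.0282). There was 0 overlap among loci that rose (0.0262 expected), and 0 loci passed in opposite directions. Across the 24091 loci the log2 fold changes of the diet comparisons had a Pearson correlation of 0.057, which is across genes, and genes are not independent replicates.

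Genes that fell at 6 weeks were among those whose diet effect differed between the times. The diet effect on Slc2a5 was higher at 22 than at 6 weeks by 3.28 ± 0.60 on the log2 scale (adjusted p = 0.0409), that on Fabp5 by 2.40 ± 0.41 (adjusted p = 0.0381), that on Mogat2 by 2.42 ± 0.43 (adjusted p = 0.0381) and that on Thrsp by 2.01 ± 0.35 (adjusted p = 0.0381). The fatty acid synthesis list had a median difference of 1.58, with 2 of 11 genes passing over all loci and 8 when adjusted over the list alone (camera adjusted p = 1.8e-16, and adjusted p = 0.07 with an estimated correlation). Among lysosome genes, the diet effect was higher at 22 weeks for Lipa (1.10 ± 0.15, adjusted p = 0.017), the Ctsd locus (1.07 ± 0.17, adjusted p = 0.0261) and the protease gene Ctsb (0.79 ± 0.15, adjusted p = 0.0478). At 6 weeks all Western-diet libraries lay below all normal-diet libraries for Lipa and the Ctsd locus. The Ctsd locus then stood at 725 ± 18.4 CPM on normal and 592 ± 69.1 CPM on Western diet. The differences of these 2 loci therefore hold lower Western-diet values at 6 weeks as well as higher ones at 22 weeks. The lysosome list had a median difference of 0.32 (camera adjusted p = 7.3e-12, and adjusted p = 0.07 with an estimated correlation), with 3 genes passing over all loci and 11 when adjusted over the list alone. Dio2 (-1.91 ± 0.35, adjusted p = 0.0418) and the locus of Rhoq (-2.00 ± 0.27, adjusted p = 0.0149), a small GTPase, had a lower diet effect at 22 weeks. Kng2, a kininogen gene that rose at 22 weeks, had a diet effect higher by 2.50 ± 0.40 (adjusted p = 0.0325). In all, 44 loci passed, 35 with a higher and 9 with a lower diet effect at 22 weeks (15 and 11 with scaling to equal totals), and 13 lists passed with the preset correlation, 0 with an estimated correlation in camera and 5 in fry. The number of loci lay between 3 and 74 when 1 of the 16 libraries was left out. It was 0 in edgeR without the 4 libraries highest in thymocyte or B cell genes, against 2880 loci at an unadjusted p under 0.05 in the main test and 493 with DESeq2.

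Between 6 and 22 weeks 11247 of 24091 loci differed on normal and 10561 on Western diet, in a comparison that also separates ages of 14 and 30 weeks and the library series. Endothelial genes were higher at 22 weeks: Vwf, von Willebrand factor, rose on normal diet from 219 ± 42 to 830 ± 159 CPM (1.92 ± 0.19, adjusted p = 1.42e-06) and on Western diet from 238 ± 43.3 to 726 ± 94.1 CPM (1.61 ± 0.19, adjusted p = 7.48e-06). The receptor gene Tie1 rose on both diets (1.42 ± 0.13 and 1.49 ± 0.13, adjusted p = 8.84e-07 and 6.9e-07). Of 17 endothelial markers, 10 rose and 2 fell on normal diet and 9 rose and 1 fell on Western diet (camera adjusted p = 0.0044 and 0.00018, and adjusted p = 0.85 and 0.32 with an estimated correlation). Of 20 macrophage markers 10 rose and 1 fell on normal diet, and 11 rose and 1 fell on Western diet (camera adjusted p = 0.024 and 0.0023, and adjusted p = 0.85 and 0.66 with an estimated correlation).

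Lipid-laden macrophage genes, lysosome genes and LXR targets were higher at 22 weeks as well. Trem2 rose on Western diet from 3.28 ± 1.9 to 47.3 ± 6.52 CPM (3.85 ± 0.50, adjusted p = 2.19e-05), and the Gpnmb locus from 74.8 ± 53.3 to 736 ± 93.8 CPM (3.30 ± 0.46, adjusted p = 4.16e-05). Of the 18 lipid-laden macrophage genes 16 rose and 1 fell on Western diet (camera adjusted p = 1.6e-07, and adjusted p = 0.19 with an estimated correlation), while on normal diet 11 rose and 3 fell and the list did not pass (adjusted p = 0.11). Of 35 lysosome genes 26 rose and 1 fell on Western diet and 15 rose and 2 fell on normal diet (camera adjusted p = 2.4e-09 and 0.039, and adjusted p = 0.19 and 0.85 with an estimated correlation). Abcg1 rose from 30.5 ± 6.36 to 115 ± 23.7 CPM on normal and from 43.5 ± 4.96 to 195 ± 24 CPM on Western diet (1.92 ± 0.17 and 2.17 ± 0.17, adjusted p = 7.37e-07 and 3.45e-07). Immediate early genes, which respond within minutes to stress or handling, rose in 16 of 18 cases on normal and 9 of 18 on Western diet (camera adjusted p = 4.5e-06 and 0.0051, and adjusted p = 0.85 and 0.69 with an estimated correlation), with Junb going from 20.7 ± 3.71 to 121 ± 51.5 CPM on normal diet. Of 12 LXR targets 8 rose and 4 fell on normal diet and 8 rose and 1 fell on Western diet (camera adjusted p = 0.047 and 0.00011, and adjusted p = 0.85 and 0.19 with an estimated correlation). On Western diet, further lists that passed had medians of 1.03 (fatty acid synthesis genes), 1.03 (modulated smooth muscle genes), 1.62 (neutrophil markers), 1 (cytokines), 1.19 (antigen presentation), 0.30 (fibroblast and matrix genes) and -0.37 (contractile smooth muscle genes, whose score difference of -0.41 was -0.25 without Western-diet replicate 2 of 22 weeks). With an estimated correlation their adjusted p values were 0.66, 0.32, 0.24, 0.66, 0.9, 0.9 and 0.9. The Apoe and Tomm40 locus rose on both diets (1.12 ± 0.11 and 1.21 ± 0.11, adjusted p = 9.95e-07 and 6.88e-07).

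Brown fat and mitochondrial genes were lower at 22 weeks on normal diet. Of 13 brown adipocyte genes 10 fell, Fabp3 from 57.4 ± 8.35 to 7.7 ± 4.4 CPM (-2.90 ± 0.36, adjusted p = 1.29e-05), and of 27 oxidative phosphorylation subunits 18 fell (camera adjusted p = 0.00011 and 2.9e-05, and adjusted p = 0.85 for both with an estimated correlation). On Western diet these lists did not pass (adjusted p = 0.11 and 0.44). Skeletal muscle markers fell in 7 of 11 cases on normal diet (camera adjusted p = 0.013, and adjusted p = 0.85 with an estimated correlation). On Western diet the muscle list did not pass. Its score went the other way, from -0.76 ± 1.73 at 6 weeks to 1.16 ± 1.25 at 22 weeks (mean ± SD). Col2a1 was at most 0.406 CPM in any 6-week library and at 223 ± 127 CPM on Western diet at 22 weeks. Vaultrc5, a vault RNA, fell from 169 ± 11.8 to 1.78 ± 0.164 CPM on normal and from 150 ± 45.2 to 1.87 ± 0.329 CPM on Western diet (-6.56 ± 0.23 and -6.33 ± 0.23, adjusted p = 2.58e-10 and 3.73e-10). Liver transcripts such as Alb, the gene of serum albumin, were also higher in some 6-week libraries, with up to 473 CPM against at most 14.2 CPM at 22 weeks.

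In all, 11247 loci passed on normal diet (5792 higher and 5455 lower at 22 weeks) and 10561 on Western diet (5274 higher and 5287 lower; 3694 higher and 7414 lower with scaling to equal totals), with no overlap of the times in 44% and 40.5% of loci against 2.86% by chance. Of these, 7934 passed on both diets in the same direction and 38 in opposite directions, and 8 lists passed on normal and 13 on Western diet with the preset correlation, 0 with an estimated correlation in camera and 13 on each diet in fry. With correction for GC content, chosen after seeing the data, 7490 and 6408 loci passed. Of these, 5805 and 4916 had also passed in the same direction without it. Every 6-week library carried 1 library code and every 22-week library another, so time, age and library series cannot be told apart, and no within-series value could be had. Ribosomal, signal recognition, 7SK and RNase P RNA took 2.94% to 4.81% of counts in the 6-week and 7.3% to 15.6% in the 22-week libraries.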

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

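In this part the tests on GC content, library batch, fat cell share, collection time, and the models with a muscle or a brown fat score were chosen only after the result was seen, while the test on unannotated RNA was set out beforehand. The score models used all 16 libraries, a form taken after a model of the 8 libraries of 22 weeks alone had left the muscle question open.

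Many loci differed between 6 and 22 weeks: 11247 on normal and 10561 on Western diet. After correction for GC content 7490 loci passed on normal diet, 5805 of them shared with the uncorrected test in the same direction, and 6408 on Western diet with 4916 shared, which argues against GC content as the whole cause. The log2 fold changes had a rank correlation with GC content of 0.53 on normal and 0.54 on Western diet. After correction it was 0.036 and 0.029. A part of the loci called without correction was thus lost along with a shift that follows GC content. The correction removes such a shift whatever its cause, so whether it was a bias of the libraries or a real difference stays open. Loci without an annotated transcript held 9.01% to 10.2% of counts in the 6-week and 6.17% to 8.57% in the 22-week libraries, so that share did differ. Of loci with an annotated transcript, 53.5% passed on normal diet, which argues against another share of unannotated RNA as the whole cause. Unspliced RNA can also fall in loci with an annotated transcript, and its share was not tested. The number of library codes holding both times was 0, so library batch, age and time on diet cannot be told apart, and a biological effect of age or diet duration stays open and untested.

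Fatty acid synthesis genes were lower on Western diet at 6 weeks, with a score difference of -1.02 (exact p = 0.0286, the smallest the 8 libraries can give). The score fell further than that of adipocyte markers, by -0.66 between them (exact p = 0.0286), while the adipocyte score differed by -0.36 (exact p = 0.114). A smaller share of fat cells alone is therefore argued against. The 2 arms of the clock, of Arntl and of Dbp with the Per genes, lay 1.45 apart between the diets (exact p = 0.0286), at 0.57 and -0.88. Collection at another time of day and a diet effect on the clock and on lipogenesis cannot be told apart, because no collection time is given in the sources used here.

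Oxidative phosphorylation subunits were higher on Western diet at 22 weeks, with a score difference of 0.86 ± 0.22 SE (exact p = 0.0286). With the skeletal muscle score in the model of 16 libraries the difference was 0.96 ± 0.30, with a slope of -0.04 ± 0.07. That slope also rests on the 6-week libraries, among them Western-diet replicate 4 with a muscle score of -3.31 and a subunit score of 0.43. With the 8 libraries of 22 weeks alone the difference was 0.69 ± 0.49 and the slope 0.06 ± 0.15. The models decide neither way, so muscle RNA is not excluded. With a brown adipocyte score that left out Cox7a1 and Cox8b the difference was 0.05 ± 0.13 and the slope 0.78 ± 0.09, so a larger amount of brown fat RNA in the Western-diet libraries is a candidate explanation. Brown fat left on the aorta at dissection and a diet effect within such fat were not tested apart.

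The difference between the diet effects at 22 and at 6 weeks, tested by an interaction term, passed at 44 loci. Among those with the widest gaps were Slc2a5 (3.28), Kng2 (2.50), Nfrkb (2.45), Mogat2 (2.42) and Fabp5 (2.40) on the higher side. On the lower side were Rhoq with Gm50012 (-2.00), Dio2 (-1.91), Endov (-1.04) and Ric8b (-0.63). Of the lists, the same test passed with the preset correlation for lipid-laden macrophage genes (median difference 0.86), autophagy receptors and regulators (0.10), lysosome genes (0.32), modulated smooth muscle genes (0.43), adipocyte markers (0.73), brown adipocyte genes (1.22), skeletal muscle markers (4.30) and cholesterol synthesis genes (0.21). It also passed for LXR targets (0.24), fatty acid synthesis genes (1.58), oxidative phosphorylation subunits (1.01), cell division genes (-1.65) and immediate early genes (-0.60). The cell division score difference of -0.88 was -0.26 without Western-diet replicate 1 of 6 weeks and -0.55 without normal-diet replicate 4 of 22 weeks. That of cholesterol synthesis genes, 0.37, was 0.23, 0.59 and 0.15 without Western-diet replicates 1, 2 and 3 of 6 weeks. With an estimated correlation 0 of these lists passed in camera, against 5 in fry.

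Single libraries stood far from the other 3 of their group in 20 of 240 groups of values examined, about 12 of which chance alone would give. Western-diet replicate 1 of 6 weeks was high in Trem2 (6.09 CPM) and the Gpnmb locus (155 CPM), apart in its circadian clock score (-0.39), and low in total counts (64.6, in units of 1e6). Normal-diet replicate 3 of 6 weeks stood apart in Psap (1100 CPM) and in the scores of autophagy core (-0.04) and lysosome genes (-0.22). Western-diet replicate 2 of 22 weeks stood apart in Thrsp (1450 CPM), Hsd11b1 (70.8 CPM) and the fibroblast score (-0.09), and replicate 3 in Cntfr (13.2 CPM) and the cardiac muscle score (2.85). Others were Dio2 (343 CPM) and Insig1 (139 CPM) in Western-diet replicate 4 of 6 weeks, and Junb (197 CPM) and Col2a1 (85.3 CPM) in normal-diet replicate 1 of 22 weeks. The last were the Apoe and Tomm40 locus (93 CPM) in normal-diet replicate 3 of 22 weeks, and the scores of T and NK cells (0.75) in normal-diet replicate 2 of 6 weeks, of neutrophils (-0.31) in replicate 1 of that group, and of skeletal muscle (-0.72) in Western-diet replicate 4 of 22 weeks.

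Loci without a gene name, which entered no comparison, held 0.606% of all counts.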

How the results depend on the processing

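Chosen only after the result was seen were the tests with limma on log2(FPKM + 0.5) in its role as an alternative, DESeq2, filterByExpr, GC and length correction, loci of 1 gene, counts divided by 4, and the omission of 4 libraries. Where a count or direction changed below, the cause was not tested, except that a stricter filter tests fewer loci and a minimum fold takes a part of the same loci.

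The alternatives named with limma changed the test from edgeR as well, so they are to be read against limma on log2(FPKM + 0.5), which gave 90, 146 and 32 loci for diet at 6 weeks, at 22 weeks and their difference. For diet at 6 weeks the 68 loci became 108 with limma on log2 FPKM at a pseudocount of 1, 197 with limma and array weights, 12 with a replicate block, 458 with DESeq2 and 24 without the 4 libraries highest in thymocyte or B cell genes. For diet at 22 weeks the 55 loci became 146 with limma on log2(FPKM + 0.5), 140 and 147 with the same limma test at pseudocounts of 0.1 and 1, 201 with limma and array weights, 829 with DESeq2 and 318 without those 4 libraries. They became 12 with no filter, 25 with equal totals, 25 with filterByExpr, 23 with robust spread without trend and 23 at a fold of at least 2. With the 8 libraries alone, and with a replicate block, edgeR gave 0, against 3437 loci at an unadjusted p under 0.05 in the test of all libraries. The replicate numbers did not pair the libraries: the own number correlated best in 0 or 1 of 4 cases, with correlations of -0.202 to 0.12.

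The 44 loci with different diet effects became 32 with limma on log2(FPKM + 0.5) and 26 with that test at a pseudocount of 0.1, 26 with no filter and with equal totals in edgeR, 11 with robust spread, 16 with filterByExpr and 493 with DESeq2. In edgeR they became 0 with a replicate block and 0 without the 4 libraries, against 2880 at an unadjusted p under 0.05 with all libraries. The time comparisons went from 11247 and 10561 loci to 4101 and 3936 at an FPKM of 5 or more, 4989 and 4315 at a fold of at least 2, and 7490 and 6408 with GC correction. The overlap of the diet comparisons, 1 locus, was 2 with limma at pseudocounts of 0.5 and 1, 3 with limma and array weights, 19 with DESeq2 and 5 without the 4 libraries. It was 0 with no filter, robust spread, the 8 libraries alone, a replicate block, a fold of at least 2 and filterByExpr.

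The numbers of passing lists (12, 18, 13, 8 and 13 in the order of diet at 6 weeks, at 22 weeks, their difference, and time on normal and Western diet) were 0, 2, 0, 0 and 0 in camera with an estimated correlation and 2, 9, 5, 13 and 13 in fry. At an FPKM of 5 or more they were 5 at 6 weeks, 3 for time on normal and 2 for time on Western diet. With no filter, 15 passed for time on normal diet.

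With each library left out in turn, 30 to 74 loci passed for diet at 6 weeks: 30 without Western-diet replicate 2 or normal-diet replicate 1, and 44, 43 and 41 without normal-diet replicates 2, 3 and 4. For diet at 22 weeks 0 to 429 passed: 0 without normal-diet replicate 2, 26 without replicate 1, 429 without replicate 4, and 20, 16, 35 and 36 without Western-diet replicates 1 to 4. For the difference 3 to 74 passed: at 22 weeks 20 and 19 without Western-diet replicates 1 and 2, and 14 and 3 without normal-diet replicates 1 and 2. At 6 weeks it was 6, 3, 7 and 74 without Western-diet replicates 1 to 4, and 5, 4, 10 and 4 without normal-diet replicates 1 to 4. Time gave 9982 to 10550 on normal and 9538 to 10094 on Western diet. Lists numbered 11 to 15, 17 to 20, 11 to 15, 5 to 10 (5 without normal-diet replicate 3 of 22 weeks) and 10 to 14, and the overlap 0 to 3.

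Of 166 named results that passed, 3892 of 4516 comparisons with an alternative kept direction and side of the threshold, 624 lost the threshold and 0 changed direction. Of 166 that did not pass, 4536 of 4710 stayed, 163 came to pass and 11 changed direction. The 0 among those that passed is in part fixed by the selection. Genes named by fold in the diet and time comparisons had no overlap between the groups, so leaving out 1 library could hardly turn their direction. These numbers also pool the diet with the time comparisons. Cd2 at 22 weeks (-0.68) was 0.076 with limma at a pseudocount of 0.1, 0.10 with limma and array weights, 0.356 with a replicate block, 0.70 without the 4 libraries and -1.166 to 1.169 with single libraries left out, the ends being without Western-diet replicate 1 and without normal-diet replicate 4. The diet effect difference of the Apoe and Tomm40 locus (0.08) was -0.013 at an FPKM of 5 or more and -0.057 with equal totals. At 6 weeks Myl9 was 0.037 and Tagln 0.085 with limma and quantile normalization, while single libraries left out gave Itgam -0.252 and Aif1 -0.304 without Western-diet replicate 3, up to 1.404 for Itgam without Western-diet replicate 2 and 1.73 for Aif1 without normal-diet replicate 2.

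With scaling to equal totals the median log2 fold change of all loci was -0.18 for the difference of the diet effects and -0.23 for time on Western diet, against -0.05 and -0.02 with TMM, and it moved by less than 0.1 in the other comparisons. The balance of directions depended on the setting. For diet at 6 weeks 15 higher and 53 lower became 25 and 42 with equal totals, 31 and 59 with limma on log2(FPKM + 0.5), 94 and 103 with limma and array weights, and 237 and 221 with DESeq2. For diet at 22 weeks 42 and 13 became 16 and 9 with equal totals, and for the difference 35 and 9 became 15 and 11. For time on normal diet 5792 and 5455 became 4252 and 7914 with limma on log2(FPKM + 0.5), and on Western diet 5274 and 5287 became 3669 and 8056 with that test and 3694 and 7414 with equal totals.

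Division of the counts by 4 gave 64, 55 and 44 loci for the diet comparisons and their difference. The effect of depth was not tested by simulation; in the simulated data at the depth of these libraries 12% and 16% of loci changed by a fold of 1.5 were recovered at 6 and at 22 weeks.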

Other observations

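Further genes passed in the comparisons. At 22 weeks S100b, a calcium-binding protein of fat, glia and cartilage, rose by 1.25 ± 0.19 (edgeR adjusted p = 0.0207), and the diet effect on Acss2, which makes acetyl-CoA from acetate, was 2.08 ± 0.34 higher than at 6 weeks (edgeR adjusted p = 0.0381). Fasn rose between 6 and 22 weeks on Western diet by 2.12 ± 0.29 (edgeR adjusted p = 3.46e-05), from 5780 ± 1100 to 25200 ± 11900 CPM.

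In this part the tests with other splits of the libraries were set out beforehand, and the model of the lysosome score with a macrophage score was chosen only after the result was seen. The hypothesis was that lysosome genes were higher on Western diet at 22 weeks because of a larger share of macrophages alone. The lysosome score differed by 0.44 ± 0.07 SE between the diets (exact p = 0.0286). With the macrophage score in a model of all 16 libraries it differed by 0.39 ± 0.07, with a slope of 0.11 ± 0.06. That slope also rests on the 6-week libraries, among them Western-diet replicate 3 with a macrophage score of 0.56 and a lysosome score of -0.2. In a model of the 8 libraries of 22 weeks the lysosome score differed by 0.31 ± 0.08, with a larger slope of 0.28 ± 0.12. A rise that follows the general macrophage markers alone is thus argued against. That score measures the share of macrophages imperfectly, which leaves a part of its effect in the adjusted difference. A larger share of macrophages that these markers follow poorly, such as lipid-laden ones, is therefore not excluded. More lysosomal RNA per macrophage, or in other cells, may also play a part and was not tested.

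The libraries were also split in other ways, keeping the group sizes. For diet at 6 weeks 1 of 35 splits, the real one, gave as many as 68 loci, and the highest other gave 3. For diet at 22 weeks 1 of 35 gave as many as 55, and the highest other gave 6. For time 1 of 35 splits gave as many as 11247 loci on normal and 1 of 35 as many as 10561 on Western diet, and the highest other gave 1 on each. For the difference of the diet effects 2 of 100 splits gave as many as 44. The other one, with 71, exchanged the diet labels at 22 weeks, which tests the sum of the diet effects. In the diet and time comparisons the real split thus had a share of 2.86%, the smallest that 35 splits can give. Chance is less likely at that share but not excluded. Every other time split put libraries of both times in each group, which widens the spread within groups, so few loci could pass. The 55 loci of diet at 22 weeks also became 0 without normal-diet replicate 2. The splits for the difference exchanged diet labels within each time, so they test for no diet effect at either time. A diet effect at 1 time alone could set the real split apart, so these splits cannot decide whether chance gave the 44.

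For the counts of passing lists chance was not excluded. As many as the real 12 lists at 6 weeks came from 14 of 35 splits (highest other 15), and as many as the 18 at 22 weeks from 5 of 35 (highest other 19). As many as the 13 of the difference came from 47 of 100 (highest other 19), as many as the 8 of time on normal diet from 25 of 35 (highest other 16), and as many as the 13 of time on Western diet from 13 of 35 (highest other 19). The number of lists that pass with a preset correlation therefore does not separate these groups from other groupings of the same libraries.

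Markers of other tissues, chosen after their values were seen, varied between single libraries. The cardiac myosin Myh6 stood at 312 CPM in Western-diet replicate 3 and 220 CPM in normal-diet replicate 4 of 22 weeks, and Dbh, an enzyme of noradrenaline synthesis, at 415 and 280 CPM in Western-diet replicates 2 and 4 of 6 weeks. Adipoq averaged 294 CPM on normal and 298 CPM on Western diet at 6 weeks, and 220 and 241 CPM at 22 weeks.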
